A study of Mus musculus with 41 samples.

How the data were processed

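The counts per gene were deposited by the authors as 1 table for each library. Per the submitters' processing notes, reads were aligned to the mouse genome mm10 with STAR 2.0.0e and counted per gene with HTSeq. The gene annotation and the strand setting of the counting are not given in the sources used here, so overlapping genes on opposite strands and pseudogenes cannot be separated. Of the listed entries, 32531 named genes were used, while 5 summary lines of the counting program and 1 entry named unknown, with a count of 0, were left out. Genes with the mitochondrial genome as their origin are absent from the tables. Counts of Rpl10a include those of the transgene.

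Library sizes were scaled by TMM in edgeR 4.0.16 (R 4.3.3), genes with few counts were removed by filterByExpr, and groups were compared by edgeR quasi-likelihood F tests with Benjamini-Hochberg adjusted p under 0.05. Each time was fitted with its 3 groups, the difference of differences and the saline libraries at both times in 1 fit of the 6 immunopurified groups, and purified against input RNA in the 3 saline groups. All cocaine means the average of the escalating and nonescalating groups. The log2 fold change ± standard error comes from the fit. CPM are counts per 1e6 counts, given as mean ± SD over libraries. DESeq2 1.42.0 was run as a second tool. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, again with the correlation estimated from the data, and with fry. Adjusted p-values of edgeR, DESeq2 and limma are given unless a test is named. Single values per library were compared by two-sided exact permutation tests. The groups, comparisons, gene lists, thresholds and most alternative settings were fixed before the data were examined.

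The 35 lists comprise markers of D1, D2 and shared medium spiny neurons, striosome and matrix, interneurons, cortical neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelial and mural cells, and ependymal cells. They also comprise red blood cell, sex-linked, immediate early, glutamate receptor, GABA receptor, dopamine and cyclic AMP, neuropeptide, potassium, sodium and calcium channel, postsynaptic and synaptic vesicle genes. The remaining lists are oxidative phosphorylation, mitochondrially encoded, ribosomal protein, endoplasmic reticulum stress, heat shock, circadian, glucocorticoid-responsive, cholesterol, chromatin, interferon and cilium genes. The mitochondrially encoded list has 0 members in the tables, so it could not be tested. Lists with fewer than 3 tested members were left out, which removed red blood cell and microglial genes at 24 h and red blood cell genes for purified against input RNA.

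Genes named are, among those called, the 10 higher and the 10 lower with the lowest p. Where fewer than 5 genes were called, the 5 with the lowest p are added as not passing. Up to 4 genes with the lowest p of each list described, and 14 genes fixed in advance (Drd1, Drd2, Rpl10a, Fos, Fosb, Arc, Egr1, Npas4, Nr4a1, Pdyn, Tac1, Penk, Bdnf and Cartpt), complete the set. Genes named only by clone or prediction numbers of the Gm, Rik and LOC kinds were passed over. Asic1, the potassium channel genes and the synaptic vesicle genes of the saline comparison over time were picked after their values were seen. Some genes that meet this rule are not reported here. Positions are those of GENCODE M21 on GRCm38, which is mm10.

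The methods were tested on simulated data in which 100 genes were changed 2-fold and 100 changed 4-fold. All 200 were drawn from genes with a mean CPM of at least 5, so the recovery does not cover genes with fewer counts. At 24 h, 23% of the 2-fold and 72% of the 4-fold changes were recovered for escalating against saline, 26% and 83% for nonescalating against saline, and 38% and 84% for all cocaine. At 1 month these were 41% and 94% for escalating against saline and 66% and 97% for all cocaine. For purified against input RNA they were 3% and 37%. False calls made up 2.06% to 5.59% of the calls. Each simulated gene had the same spread in every group and no library was made to stand apart, so this share need not hold in the real data. When ribosomal protein genes were shifted 1.5-fold, camera found that list and called 1 other list of 32. The simulated genes varied independently, whereas ribosomal protein genes had an estimated correlation of 0.316 in the real data at 24 h. The simulation therefore does not show how often camera calls lists of correlated genes falsely. A comparison of 128 pairs of libraries within groups found no duplicates (lowest chi-square per degree of freedom 8.89).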

Results

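RNA bound to tagged ribosomes was profiled by sequencing. The dorsal striatum came from mice of the transgenic line CP73, in which cells that express the dopamine D1 receptor gene Drd1 carry an EGFP-tagged ribosomal protein L10a. Translating ribosome affinity purification (TRAP) pulls down the tagged polysomes with antibodies against EGFP, so that the RNA recovered comes mainly from D1 medium spiny neurons. The mice had self-administered saline or cocaine intravenously in a long-access study, and the cocaine groups are labelled nonescalating or escalating. Tissue was taken 24 h or about 1 month after self-administration. At 24 h there were 5 saline, 9 nonescalating and 5 escalating libraries. At 1 month there were 5 saline, 11 nonescalating and 4 escalating libraries. A further 2 saline inputs hold total RNA before purification and carry no time label, which makes 39 immunopurified libraries and 41 in all. In the nonescalating groups the replicate numbers restart, giving runs of 6 and 3 libraries at 24 h and of 6 and 5 at 1 month. The labels of the purified libraries call the self-administration extended, except in the second nonescalating run and the escalating group at 1 month, where that word is missing. Whether the sessions differed is not stated, so at 1 month any such difference goes with these libraries.

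The libraries held 5394332 to 23925655 counts on named genes, with a median of 11340272. Immunopurified libraries detected 11856 to 18057 genes with at least 1 count, with a median of 15588. Saline replicate 5 at 24 h stood apart from the rest, with 5394332 counts, 11856 detected genes and 37.1% of its read pairs outside annotated genes, against at most 26.8% in the other immunopurified libraries. Its mean level of glial markers (log2 of counts per 1e6 counts) was 2.05, near the top of the range of -0.22 to 2.06 in the immunopurified libraries and far below the 4.50 and 4.41 of the inputs. The first principal component held 17.6% and the second 13.7% of the variance between immunopurified libraries. Saline replicate 5 at 24 h lay at 266.7 on the first, against at most 60.51 in the others. On the second it lay at 139.5, against at most 65.07. Depth, detected genes, glial score and 9 other library measures were compared between the groups at each time. None of these 72 two-sided exact permutation tests gave an unadjusted p under 0.05. All p-values here measure only the spread between these libraries, since the labels do not say whether each library is 1 animal.

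**Figure D1:**
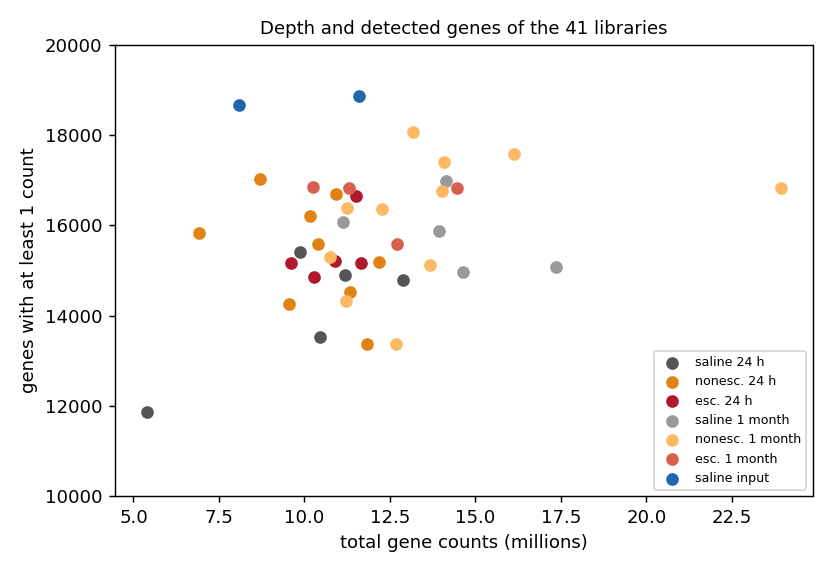
Total counts on named genes (in units of 1e6, x axis) against the number of genes with at least 1 count (y axis, which does not start at 0) in each of the 41 libraries, coloured by group. Each point is 1 library. The saline 24 h library with 11856 detected genes lies below all others.

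The saline immunopurified libraries were compared with the inputs to see which RNAs the purification enriches. D1 medium spiny neuron genes were higher in the purified RNA, and genes of D2 neurons, interneurons, oligodendrocytes and their precursors, and microglia were lower. Drd1 was 637 ± 152 CPM (counts per 1e6 counts, mean ± SD, n = 5) in saline libraries at 24 h and 630 ± 37.1 (n = 5) at 1 month, against 358 ± 80.1 (n = 2) in the inputs, a log2 fold change of 0.84 ± 0.22 (standard error, as for all fold changes here). Tac1, which encodes substance P, rose by 1.96 ± 0.42 on the log2 scale, and the dynorphin precursor gene Pdyn rose by 1.55 ± 0.38. Among indirect-pathway (D2) genes, the enkephalin precursor Penk (chromosome 4, 4133531 to 4138819) fell from 905 ± 26.4 CPM in the inputs to 174 ± 23.2 at 24 h and 154 ± 40.2 at 1 month. Its log2 fold change was -2.45 ± 0.19. The adenosine receptor gene Adora2a (chromosome 10, 75316877 to 75334784) had a log2 fold change of -4.22 ± 0.37, and Drd2 (chromosome 9, 49340627 to 49408177) one of -3.00 ± 0.34.

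By list, 6 of 11 D1 markers rose and none fell, and 6 of 11 D2 markers fell and none rose. These counts were 9 and 8 when adjusted over the list alone. Of 14 oligodendrocyte markers 12 fell, among them the myelin gene Cnp (245 ± 19.5 CPM in the inputs, 24.9 ± 11.6 at 24 h and 20.2 ± 8.34 at 1 month). Falls were also called for 4 of 9 oligodendrocyte precursor markers, including Pdgfra (log2 fold change -5.27 ± 0.96), and 4 of 12 microglial markers, including Cx3cr1 (-4.995 ± 1.26). The same held for 4 of 14 interneuron markers, including the choline transporter gene Slc5a7 (-5.25 ± 1.05) and Lhx6 (-4.74 ± 0.95), and for 5 of 13 astrocyte markers, including Slc1a2 (-2.56 ± 0.43). When adjusted over the list alone, 14 oligodendrocyte, 6 precursor, 6 microglial, 11 interneuron and 10 astrocyte markers were lower. Camera gave adjusted p = 3.52e-08 for the D1 list, 7.71e-08 for D2, 1.18e-14 for oligodendrocytes, 1.63e-05 for their precursors, 4.57e-08 for microglia, 1.08e-07 for interneurons and 1.4e-06 for astrocytes. With an estimated correlation the D1 and D2 lists kept adjusted p = 0.0209, oligodendrocytes 0.0185, precursors 0.031, microglia 0.0282 and interneurons 0.00952, while astrocytes had adjusted p = 0.135.

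Of 19 genes shared by all medium spiny neurons, 8 rose and 1, Rgs9 (a regulator of G protein signalling), fell (-1.52 ± 0.17). The list was called up (camera adjusted p = 1.37e-05, adjusted p = 0.135 with an estimated correlation). Synaptic genes were higher as groups: 9 of 39 postsynaptic scaffold and plasticity genes rose, led by the kinase gene Camk2a (1.12 ± 0.15), and 6 of 32 synaptic vesicle genes rose, led by Rab3a (1.26 ± 0.21). Camera gave 1.98e-08 and 1.01e-05 for these lists, and adjusted p = 0.133 and 0.211 with an estimated correlation. Oxidative phosphorylation genes had a positive fold change in 77 of 79 members with 6 called, and ribosomal protein genes in 72 of 79 with 3 called, among them Rpl10a (2.23 ± 0.45), whose reads include those of the transgene. Their camera values were 7.86e-15 and 1.47e-08, with adjusted p = 0.205 and 0.275 with an estimated correlation. In the dopamine and cyclic AMP list 8 genes rose and 4 fell (camera 9.22e-05, adjusted p = 0.135 with an estimated correlation), with Gnas among the latter (-1.67 ± 0.27). Immediate early genes were called up (0.000339, adjusted p = 0.164 with an estimated correlation) with 2 members called, Egr1 (1.41 ± 0.34) and Egr3 (1.14 ± 0.25). The counts of these lists adjusted over the list alone were 11 higher and 1 lower for shared markers, 12 higher for postsynaptic, 9 for vesicle, 13 for oxidative phosphorylation and 2 for ribosomal genes. They were 14 higher and 4 lower for the dopamine list and 4 higher for immediate early genes.

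Smaller groups were also called. Striosome and matrix markers were positive in 11 of 16 (camera 0.0103, 0.0627 without input replicate 2), endothelial and mural markers in 13 of 13 with 0 called (median 2.28, 0.0161, 0.0963 without saline 24 h replicate 5) and heat shock genes in 12 of 18. The heat shock list was called up (0.0469) with a median of 0.47, 2 members higher and 1 lower, while its mean was -0.06. It was lost without saline 24 h replicates 1 (0.0665) and 5 (0.0891), saline 1 month replicates 2, 3 and 4 (0.0757, 0.0544 and 0.0581) or input replicate 1 (0.116). Ependymal and choroid plexus markers were negative in 4 of 6 (0.0321, 0.0654 without input replicate 2) and sex-linked genes in 5 of 5 (0.0244, 0.0547 without saline 24 h replicate 6 and 0.147 without input replicate 1). With an estimated correlation these 5 lists had adjusted p = 0.233, 0.574, 0.31, 0.164 and 0.205 in this order. Adjusted over the list alone, 3 striosome genes and 3 heat shock genes were higher, and 1 heat shock, 1 ependymal and 2 sex-linked genes lower. The lists not called were cortical markers (0.661), glutamate receptors (0.906), GABA receptors (0.599), neuropeptides and their receptors (0.825), potassium (0.453), sodium (0.885) and calcium channels (0.304), endoplasmic reticulum stress (0.0965), circadian clock (0.135), glucocorticoid-responsive (0.506), cholesterol synthesis (0.906), chromatin (0.158), interferon (0.772) and cilium genes (0.599).

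In edgeR, 282 genes were higher and 430 lower in purified RNA among 15305 tested. Penk had adjusted p = 1.95e-05, Adora2a 3.72e-05, Drd2 0.000268, Tac1 0.0184, Pdyn 0.0307 and Drd1 0.0444. The other genes with the lowest p among those higher were Nrsn2, Sh3bgrl3, Wfs1, Grina, Ncdn, Ptk2b, Phyhip and Rgl1 (log2 fold changes of 1.12 to 1.99). Among those lower they were the carbonic anhydrase gene Car2 (-3.88 ± 0.34), the prostaglandin D synthase gene Ptgds (-6.54 ± 0.62, 57.3 ± 17.6 CPM in the inputs), the noncoding RNAs Snhg11 (-4.001 ± 0.374) and Rian (-2.62 ± 0.24), Trank1, Anln and the sequence records AK140265 and DQ539915. The size of this count depended on single libraries of both kinds: it was 43 without input replicate 1 and 49 without input replicate 2, 2302 without saline 24 h replicate 5, and 458 and 468 without saline 1 month replicates 1 and 3. Saline libraries at 24 h alone gave 12 genes against the inputs, all lower, and those at 1 month alone 2951, most of them higher. DESeq2 also called more genes higher than lower. Drd1 lost its call without any of 9 libraries (adjusted p of up to 0.569, without input replicate 2), Tac1 without either input (0.207 and 0.293), Rpl10a likewise (0.247 and 0.202), Egr1 likewise (0.354 and 0.24) and Pdyn without either input (0.325 and 0.318) or saline 1 month replicate 1 (0.0548). Genes higher in purified RNA that lost their call were Nrsn2 (0.0778), Sh3bgrl3 (0.0778), Wfs1 (0.102), Grina (0.0783), Ncdn (0.119), Ptk2b (0.102), Phyhip (0.152) and Rgl1 (0.133), each without input replicate 1. Of these, Grina (0.101), Ptk2b (0.0965), Phyhip (0.054) and Rgl1 (0.101) also lost it without input replicate 2. The inputs carry library numbers apart from the rest, and any difference in handling cannot be told apart from the purification.

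**Figure D2:**
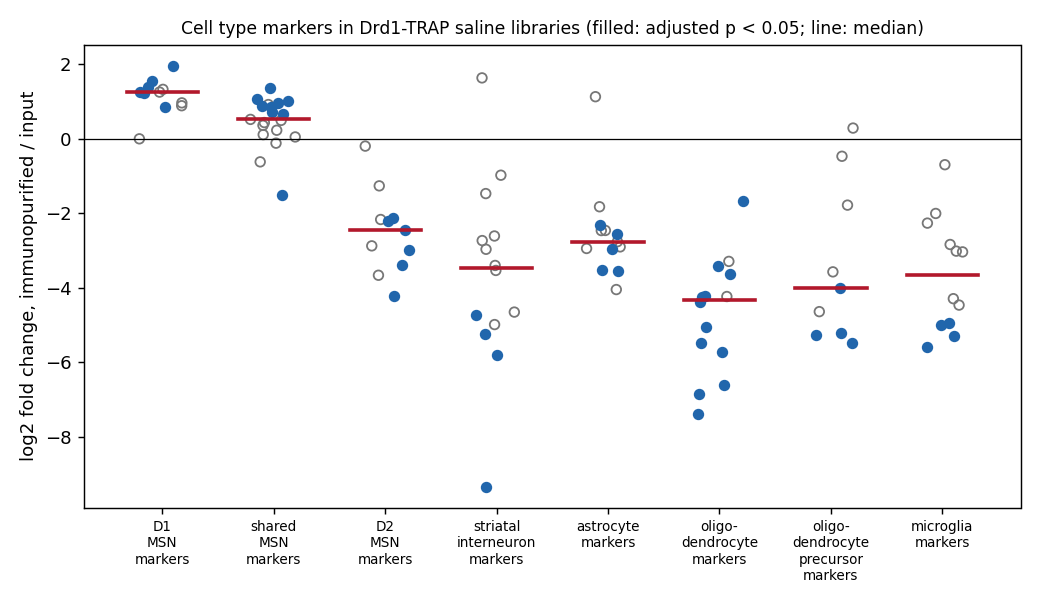
Log2 fold change (y axis) of each marker gene in 8 lists (x axis; MSN, medium spiny neuron) between 10 saline immunopurified libraries and 2 inputs. Each point is 1 gene, filled at an adjusted p under 0.05, and the red line is the median of the list, 1.25 for D1 and -2.45 for D2 markers.

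At 24 h all cocaine libraries together were compared with saline, since the study contrasts mice given cocaine with mice given saline. In this comparison 6 genes were lower after cocaine and 0 higher. Ttc7b (chromosome 12, 100300770 to 100520826, protein coding), whose product is part of a complex that brings phosphatidylinositol 4-kinase to the plasma membrane, was 420 ± 156 CPM (SD, n = 5) in saline libraries, 215 ± 42.7 (n = 9) in nonescalating and 208 ± 24.6 (n = 5) in escalating ones. Every saline library (lowest 308.5) lay above every cocaine library (highest 288.2), and the log2 fold change was -0.998 ± 0.158. The cyclic AMP phosphodiesterase gene Pde4a (chromosome 9, 21165714 to 21213248) was 142 ± 41.2 CPM after saline, 76.1 ± 11.8 in nonescalating and 77.1 ± 10.4 in escalating libraries, a fold change of -0.90 ± 0.16. The transcription factor gene Klf7 (chromosome 1, 64029447 to 64122282) was 130 ± 68.3, 56.3 ± 20 and 51.2 ± 3.35, a fold change of -1.29 ± 0.24. The other genes were Nnat, which encodes a small membrane proteolipid (chromosome 2, 157560078 to 157562522), the adhesion receptor gene Adgrd1 (chromosome 5, 129096750 to 129204599) and the metalloproteinase gene Mmp24 (chromosome 2, 155775342 to 155818366).

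Among 13437 genes tested, edgeR gave adjusted p = 0.0207 for Ttc7b and Adgrd1, 0.039 for Nnat and Pde4a, and 0.0461 for Klf7 and Mmp24. An unadjusted p under 0.05 was reached by 1842 genes, and DESeq2 called 171. edgeR called 26 genes with size factors, 30 with a filter at mean CPM of 5, 71 without a filter and 508 with all 39 purified libraries in 1 fit. Saline replicate 5 alone held 3079 CPM of Nnat, 112 of Adgrd1 and 211 of Mmp24, and without it their log2 fold changes went from -3.78 ± 0.67, -3.24 ± 0.53 and -2.26 ± 0.42 to -0.94 ± 0.41, -1.79 ± 0.44 and -0.91 ± 0.29, with adjusted p = 0.40, 0.16 and 0.264. Without that library 2 genes were called, Ttc7b (-1.04 ± 0.17, adjusted p = 0.016) and the acid-sensing ion channel gene Asic1 (-0.98 ± 0.16, adjusted p = 0.016), while Pde4a was at -0.76 ± 0.16 (0.106) and Klf7 at -0.93 ± 0.21 (0.149). The count without 1 other saline library was 89, 57, 23 and 45 (replicates 1, 2, 3 and 6), and without 1 escalating library it was 0, 2, 1, 0 and 0 (replicates 1 to 5). Ttc7b had adjusted p = 0.0744, 0.0593 and 0.0823 without escalating replicates 1, 4 and 5, and the other 5 genes lost their calls in at least 5 of the 10 fits that left out 1 library. With the first or the second run of nonescalating libraries alone, 0 genes were called.

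By list, all cocaine libraries at 24 h had negative fold changes in 28 of 39 postsynaptic genes (median -0.18) and 9 of 10 cortical markers (median -0.84). Fold changes were positive in 64 of 79 ribosomal protein genes (median 0.18) and 59 of 79 oxidative phosphorylation genes (median 0.12). Camera gave adjusted p = 0.00458, 0.0185, 0.00632 and 0.0185, and each list had adjusted p = 0.922 with an estimated correlation. The postsynaptic list was lost without saline replicates 3 (0.0727) and 6 (0.096), and the ribosomal list without saline replicates 3 (0.623) and 6 (0.303) or escalating replicate 4 (0.0676). Oxidative phosphorylation genes lost the call without saline replicates 3, 5 and 6 (0.269, 0.711 and 0.303) or escalating replicates 1 and 4 (0.0502 and 0.0762). Cortical markers lost it without saline replicates 1, 2, 3 and 5 (0.105, 0.0514, 0.0727 and 0.244) or escalating replicates 2 and 4 (0.0515 and 0.0547). D1 (0.962), D2 (0.49) and immediate early gene lists (0.878) were not called. When adjusted over the list alone, 2 postsynaptic genes were lower and no member of the other 3 called lists passed.

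**Figure D3:**
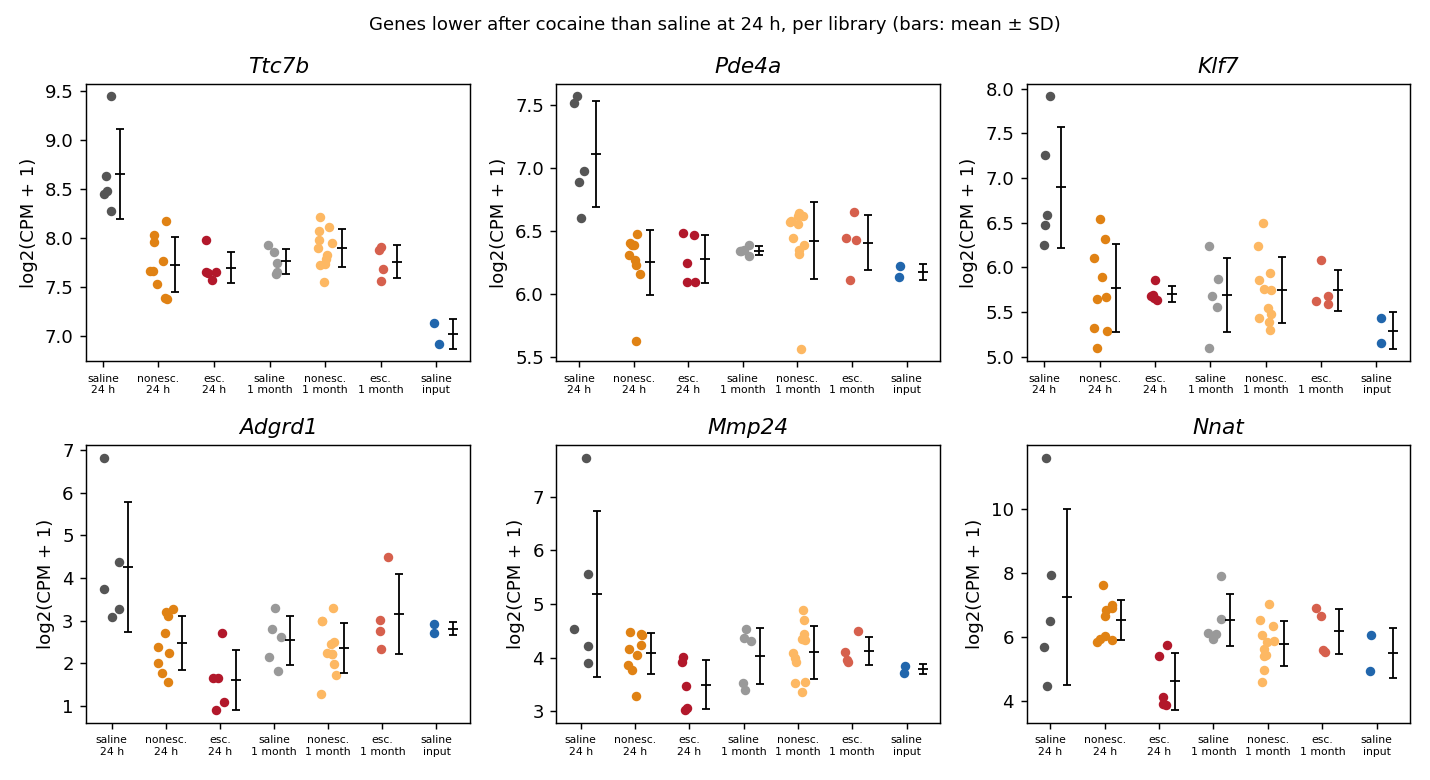
Expression (log2 of CPM + 1, y axis) in every library of the 6 genes that were lower after cocaine than after saline at 24 h, by group (x axis; nonesc., nonescalating; esc., escalating). Points are libraries and bars give the mean and SD. For Ttc7b all saline 24 h libraries (308.5 CPM or more) lie above all others, while for Nnat, Adgrd1 and Mmp24 1 saline library lies far above the rest.

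Escalating against saline libraries at 24 h asks what differs in mice whose intake rose. The gene with the lowest p was Fth1, the ferritin heavy chain gene, at 271 ± 44.5 CPM (n = 5) in escalating and 151 ± 20.1 (n = 5) in saline libraries. Its log2 fold change of 0.84 ± 0.16 did not pass (adjusted p = 0.194), nor did those of Ttc7b (-1.02 ± 0.20, 0.194), Adgrd1 (0.194), Nnat (0.239) and Csdc2 (-1.34 ± 0.29, 0.247). Ribosomal protein genes had positive fold changes in 65 of 79 members (median 0.34), with Rpl8 at 0.93 ± 0.28 and Rps9 at 1.34 ± 0.44, and oxidative phosphorylation genes in 67 of 79 (median 0.24), with Atp5c1 at 0.48 ± 0.19. Postsynaptic genes had negative fold changes in 28 of 39 members (median -0.20), with the neuroligin gene Nlgn3 at -0.58 ± 0.15, and cortical neuron markers in 9 of 10 (median -1.27), with Nptx1 at -1.29 ± 0.56. Camera called these 4 lists of 32 (adjusted p = 1.1e-05, 0.000113, 0.00178 and 0.000821), and all had adjusted p = 0.825 with an estimated correlation. No member passed over all genes, and adjusted over the list alone 1 postsynaptic gene was lower. edgeR called 0 of 13437 genes, with 1433 at an unadjusted p under 0.05, and 43 with all 39 purified libraries in 1 fit. DESeq2 called 13 higher and 34 lower. Ribosomal protein genes have many processed pseudogenes that share their reads, so single members are uncertain.

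Nonescalating against saline libraries at 24 h gave Ttc7b as the gene with the lowest p (log2 fold change -0.97 ± 0.17, adjusted p = 0.109). Pde4a (-0.91 ± 0.17), the carbonic anhydrase-related gene Car11 (-0.93 ± 0.18, 168 ± 30.7 against 316 ± 126 CPM), Nod2 (-3.84 ± 0.76) and Spred2 (-0.83 ± 0.17) followed, each with adjusted p = 0.129. Postsynaptic genes had negative fold changes in 28 of 39 members (median -0.17), with Nlgn3 at -0.56 ± 0.13 and Sorbs2 at -0.49 ± 0.17. Camera called only this list of 32 (adjusted p = 0.0212, adjusted p = 0.98 with an estimated correlation). It was lost without saline replicates 3 (0.259), 5 (0.094) and 6 (0.238). Adjusted over the list alone 1 of its genes was lower. edgeR called 0 of 13437 genes, with 1601 at an unadjusted p under 0.05, and 66 higher and 210 lower with all 39 purified libraries in 1 fit. DESeq2 called 117. Without saline replicate 1 edgeR called 2 genes, Ttc7b and Pde4a (adjusted p = 0.0454 for each).

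Across 13437 genes, the fold changes of escalating and nonescalating libraries against saline correlated with Pearson's r = 0.775 and Spearman's rho = 0.709. Genes are not independent replicates, and the comparisons share their saline libraries, which alone gave r = 0.579 in simulated counts without any difference. When the saline libraries were divided between the comparisons, the median r over 20 divisions was 0.0437, from -0.0689 to 0.101. At 1 month the same correlation was r = 0.609 over 14488 genes, with 0.543 in simulated counts and a median of 0.0345 (-0.0915 to 0.146) when the saline libraries were divided. Between the times, the fold changes against saline had r = -0.0397 for escalating, -0.0707 for nonescalating and -0.0726 for all cocaine libraries, and those of escalating against nonescalating libraries r = 0.0441.

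Escalating against nonescalating libraries at 24 h addresses escalation itself. The immediate early gene Egr1 was 1283 ± 293 CPM (n = 5) in escalating and 842 ± 212 (n = 9) in nonescalating libraries. Its log2 fold change of 0.61 ± 0.20 did not pass in edgeR (adjusted p = 0.999). The genes with the lowest p were Cyb5d1 (3.39 ± 0.73, with 163 CPM in 1 escalating library and at most 9.86 in any saline library at 24 h), Sap30bp (2.61 ± 0.67), Actl6b, a subunit of the neuronal BAF chromatin complex (-0.93 ± 0.24), Pnn (0.61 ± 0.16) and the record AK140265 (2.16 ± 0.57), all with adjusted p = 0.999. Ribosomal protein genes again had mostly positive fold changes (60 of 79, median 0.29, Rps9 1.12 ± 0.37), as did oxidative phosphorylation genes (66 of 79, median 0.27, Ndufa1 0.79 ± 0.33) and endoplasmic reticulum stress genes (15 of 25, median 0.15, the disulfide isomerase gene Pdia6 0.71 ± 0.25). Cortical neuron markers were negative in 8 of 10 (median -0.97, Tbr1 -2.20 ± 1.03). Camera gave adjusted p = 8.01e-07, 7.95e-06, 0.0382 and 0.00406. With an estimated correlation the stress list had adjusted p = 0.389 and the other 3 lists adjusted p = 0.975. Against the first nonescalating run alone the ribosomal list had adjusted p = 0.0235, the cortical list 0.0224, the oxidative phosphorylation list 0.0843 and the stress list 0.181. The cortical list was lost without escalating replicate 2 (0.165), and the stress list without escalating replicates 2 (0.165) and 5 (0.0712). No member of these 4 lists was called when adjusted over the list alone. edgeR called 0 of 13437 genes, with 537 at an unadjusted p under 0.05, and 2 with all 39 purified libraries in 1 fit. DESeq2 also called 0.

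Marker levels of the purified cell type were close between the groups. Drd1 was 621 ± 93.3 CPM in nonescalating (n = 9) and 629 ± 32.8 in escalating (n = 5) libraries at 24 h, and 576.5 ± 71.4 (n = 11) and 601 ± 68.0 (n = 4) at 1 month. Its log2 fold changes against saline lay between -0.14 ± 0.10 and -0.03 ± 0.16. Activity-regulated and peptide genes did not pass at 24 h: in all cocaine libraries the log2 fold change was -0.22 ± 0.29 for Fosb, 0.15 ± 0.37 for Arc, 0.05 ± 0.19 for Egr1, 0.49 ± 0.72 for Npas4, 0.63 ± 0.40 for Nr4a1, 0.31 ± 0.19 for Pdyn, -0.04 ± 0.27 for Tac1 and -0.13 ± 0.20 for Penk. Fos (1.99 ± 4.29 CPM in saline libraries), Bdnf (1.16 ± 1.43) and Cartpt (2.44 ± 1.98) lay so low that their fold changes of 1.21 ± 1.08, -1.40 ± 1.08 and 0.09 ± 0.82 are imprecise. Saline replicate 3 alone held 9.672 CPM of Fos, against at most 0.2012 in the other saline libraries, and 44.86 of Npas4, against at most 7.436. Without it the fold change of Npas4 was 1.88 (adjusted p = 0.281), that of Bdnf -0.37 (0.925), and Fos, with almost no saline counts left, had adjusted p = 0.0575. The fold change of Bdnf was -2.26 (0.436) without escalating replicate 5. The log2 fold change of Drd2 was -0.39 ± 0.35 and that of Rpl10a -0.14 ± 0.24. None of these 14 genes passed in any cocaine comparison at either time.

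At 1 month no gene was called in any comparison. Against saline, escalating libraries had the lowest p for Ccdc23 (2.84 ± 0.78), Gpr101, an orphan receptor gene (33.2 ± 8.48 against 53.8 ± 14.2 CPM, log2 fold change -0.71 ± 0.22), the records AK080456 and AK171960, and Rpp40, all with adjusted p = 1. Nonescalating libraries had it for the record AK161456, Lca5 (5.45 ± 1.31 against 11.5 ± 6.08 CPM, -1.09 ± 0.27), Htr5b, Med28 (-0.40 ± 0.10) and Vti1b (-0.43 ± 0.11), with adjusted p = 0.999. Between the cocaine groups the lowest p fell to Ptk7 (-1.54 ± 0.43), Bambi (2.87 ± 0.80), Grik1 (3.95 ± 1.11), the record AK046832 and Pla2g4e (-1.91 ± 0.58), with adjusted p = 1. For all cocaine libraries it fell to Lca5 (-1.06 ± 0.27), Ccdc23, Xylt2, Gpr101 (-0.62 ± 0.17) and Prmt3, also with adjusted p = 1. The log2 fold changes of all cocaine libraries against saline were -0.31 ± 0.24 for Fosb, -0.36 ± 0.44 for Arc, -0.12 ± 0.19 for Egr1, 0.01 ± 0.13 for Pdyn and -0.15 ± 0.18 for Tac1. Among 14488 genes edgeR called 0 for escalating against saline (187 at an unadjusted p under 0.05), 0 for nonescalating against saline (522), 0 between the cocaine groups (177) and 0 for all cocaine (317). DESeq2 called 0 in each.

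Some gene groups were called at 1 month. In nonescalating against saline libraries 31 of 39 immediate early genes had negative fold changes (median -0.22, Nr4a3 -0.97 ± 0.33, Egr4 -0.66 ± 0.26) and all 12 oligodendrocyte markers had positive ones (median 0.72, Ugt8a 1.46 ± 0.76, Trf 0.93 ± 0.59). Camera gave 0.0048 for each, and 0.0743 and 0.123 without saline replicate 2. Endothelial (0.0048), interferon (0.0048) and ribosomal (0.0376) lists were also called up. They were lost without saline replicates 2 (0.0743, 0.264 and 0.0743) and 4 (0.31, 0.0831 and 0.0563), and the ribosomal list without replicate 5 (0.83). All 5 lists had adjusted p = 0.972 with an estimated correlation. In escalating against nonescalating libraries, immediate early genes were positive in 24 of 39 (median 0.13, the phosphatase gene Dusp4 1.42 ± 0.45, camera 0.00358) and synaptic vesicle genes negative in 26 of 32 (median -0.07, Syp -0.28 ± 0.13, camera 0.0127), with adjusted p = 0.693 for both with an estimated correlation. The first was lost without escalating replicate 4 (0.21) and the second without escalating replicates 1 (0.191) and 2 (0.13). Escalating against saline gave ribosomal (0.000231, up, lost without saline replicate 5 at 0.18), vesicle (0.0142, down), interferon (0.0142, up) and endothelial (0.0316, up) lists, with adjusted p = 0.891 with an estimated correlation. The last 3 were lost without any of 4 to 6 of the 9 libraries, with adjusted p of up to 0.321, 0.42 and 0.6. For all cocaine 4 lists were called up, ribosomal (0.00163), interferon (0.00309), endothelial (0.0031) and oligodendrocyte (0.0161), with adjusted p = 0.907 with an estimated correlation. The ribosomal list was lost without saline replicate 5 (0.39), and the others without saline replicates 2 (0.229, 0.1 and 0.249) and 4 (0.0777, 0.414 and 0.0573) among others. No member of these lists was called when adjusted over the list alone. Red blood cell genes, a sign of blood in the tissue, were not called at 1 month (0.259 for all cocaine against saline).

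Whether the cocaine effect differed between the times was tested as a difference of differences over 15190 genes. Ttc7b was the only gene called: its nonescalating-minus-saline difference was higher at 1 month than at 24 h by 1.10 ± 0.20 on the log2 scale (adjusted p = 0.046). This test uses the same saline 24 h libraries as the cocaine comparison at 24 h, so the 2 calls of Ttc7b are not independent. At 1 month its levels were 217 ± 19.5 CPM in saline (n = 5), 239 ± 32.3 in nonescalating (n = 11) and 216 ± 24.9 in escalating (n = 4) libraries, all near the cocaine level at 24 h. Car11 (1.10 ± 0.22, 0.074), the splicing factor gene Srrm2 (0.69 ± 0.14, 0.074), Vopp1 (-1.21 ± 0.25, 0.074) and Sept4 (2.87 ± 0.62, 0.0801) came next. For escalating libraries Adgrd1 (4.62 ± 0.90, adjusted p = 0.103), Srrm2, Ttc7b, Nnat and Mmp24 (0.443 each) had the lowest p. Between the cocaine groups the lowest p fell to Cyb5d1, Il2rg and the records AK140265, AK045830 and DQ539915, with adjusted p = 1. edgeR called 1 gene for nonescalating (1786 at an unadjusted p under 0.05; DESeq2 called 73), 0 for escalating (1127; DESeq2 2) and 0 between the cocaine groups (495; DESeq2 0). The call of Ttc7b was lost without saline 24 h replicate 3 (0.068) and without saline 1 month replicates 1 (0.14), 3 (0.127) and 5 (0.0655). The nonescalating count was 8, 19, 3 and 5 without saline 24 h replicates 1, 2, 5 and 6, 2 without saline 1 month replicate 4, and 0 with the first run alone. For escalating, Adgrd1 was called without saline 24 h replicates 2 (0.0394) and 6 (0.0333) or escalating 24 h replicate 2 (0.0244).

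Of the lists, 6 were called for the escalating difference between the times, 0 for nonescalating and 3 between the cocaine groups, and all had adjusted p = 0.977 or 0.904 with an estimated correlation. For escalating against saline, the difference of 1 month minus 24 h was negative in 60 of 79 oxidative phosphorylation genes (median -0.22, camera 0.00339). It was negative in 17 of 24 cholesterol synthesis genes (median -0.31, camera 0.012). Cortical markers (0.00473, positive in 8 of 10) and interferon-stimulated genes (0.00473, positive in 18 of 21) were called up as lists. These 4 lists were lost without saline 24 h replicate 5 (0.296, 0.251, 0.114 and 0.588). The interferon list was also lost without escalating 1 month replicate 1 (0.0555). Ribosomal (0.0373, down) and postsynaptic (0.0463, up) genes lost their calls in 9 and 10 of 19 fits that left out 1 library, with adjusted p of up to 0.642 and 0.332, the highest of each without saline 24 h replicate 3. Between the cocaine groups, ribosomal (0.00384, down), oxidative phosphorylation (0.00384, down) and cortical (0.0304, up) lists were called. The first 2 were lost without escalating 24 h replicates 4 (0.251 and 0.101) and 5 (0.101 and 0.0567), and the cortical list without any of 5 libraries (up to 0.349, without escalating 24 h replicate 2). No member of these lists was called when adjusted over the list alone.

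The saline libraries themselves differed between the times: 37 genes were higher and 91 lower at 1 month than at 24 h. The splicing factor gene Srrm2 (chromosome 17, 23790532 to 23824741) was 1212 ± 149 CPM (n = 5) at 1 month and 1907 ± 429 (n = 5) at 24 h, a log2 fold change of -0.65 ± 0.12. The potassium channel gene Kcna2 (chromosome 3, 107101146 to 107115005) was 353 ± 38.3 against 558 ± 26.0 (-0.65 ± 0.13), and Car11 160.5 ± 7.74 against 316 ± 126 (-0.97 ± 0.18). Of the genes called after cocaine at 24 h, Ttc7b (-0.95 ± 0.17), Pde4a (-0.82), Klf7 (-1.31 ± 0.28), Adgrd1 (-2.62) and Mmp24 (-1.94) were called here too, and Nnat (-2.72, adjusted p = 0.0562) was not. Both comparisons use the same 5 saline libraries at 24 h, so genes high in them tend to pass in both. This overlap is no independent result. Other named genes among those lower were Zfp3 (-1.94 ± 0.35), Dph6 (-1.20 ± 0.22), Sept4 (-2.47 ± 0.51), Nlgn3 (-0.65 ± 0.14) and Sfxn3 (-0.84 ± 0.18), and among those higher the dynein gene Dync1li1 (0.86 ± 0.18), Vopp1 (0.94 ± 0.21), Med28 (0.76 ± 0.17), Abcf2 (0.95 ± 0.21), Tvp23b (2.02 ± 0.45), Zfp771 (2.83 ± 0.60), Otud3 (3.34 ± 0.76), Mif1 (4.32 ± 0.99) and Smox (5.76 ± 1.16). The means of the last 2 lay below 3 CPM in both groups.

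Postsynaptic genes had negative fold changes in 28 of 39 members between the times in saline libraries (median -0.15), with Camk2a at -0.52 ± 0.15. Camera called this list alone of 34 (adjusted p = 0.0131, adjusted p = 0.967 with an estimated correlation). It was lost without saline 24 h replicates 3 (0.179) and 6 (0.292) or saline 1 month replicate 5 (0.124). Of its members 1, Nlgn3, was called over all genes, and 2 were lower adjusted over the list alone. Among 15190 genes edgeR gave adjusted p = 0.00982 for Ttc7b, Srrm2, Zfp3, Car11 and Dph6, and 0.0207 for Kcna2. The count was 257, 323 and 379 without saline 24 h replicates 1, 2 and 6, and 7, 14, 9, 7 and 24 without saline 1 month replicates 1 to 5. It was 0 when only the saline groups were fitted (982 at an unadjusted p under 0.05), and 628 by DESeq2. The fit of the 6 groups takes 1 spread per gene for all groups, whereas saline 24 h libraries varied more for some genes. For Car11 the SD was 126 CPM in them and 7.74 in saline libraries at 1 month, while Kcna2 varied less at 24 h. Errors of this comparison may therefore be understated. Of the genes named among the 10 lowest p in each direction, Ttc7b, Srrm2, Zfp3, Car11 and Dph6 kept their calls without any 1 saline library. The others lost theirs in at least 1 of 10 such fits. The labels give no batches of processing, so a difference in handling that went with time is not ruled out by this comparison alone.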

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

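The tests that leave out saline 24 h replicate 5 and those of RNA of glial cells were chosen only after the results were seen.

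Single libraries lay far from the rest of their group in 26 of the 135 group values examined. The limit is one that chance passes in about 1 in 20 normally distributed values. CPM need not be so distributed, and the values include the genes called after cocaine at 24 h. The count of 26 is therefore no measure of an excess over chance. Saline replicate 5 at 24 h held 3079 CPM of Nnat (nearest other 244), 211.4 of Mmp24 (46.3) and 112 of Adgrd1 (19.62). Saline replicate 3 at 24 h held 694.7 CPM of Ttc7b (394.5), 44.86 of Npas4 (7.436) and 9.672 of Fos (0.2012), and saline replicate 6 had a D2 marker score of 1.607 (2.478). Nonescalating replicate 4 of the first run at 24 h held 539 CPM of Tac1, 9.927 of Bdnf, 196.9 of Nnat and 48.32 of Pde4a. In the escalating group at 24 h, replicate 1 held 57 CPM of Klf7 and 2.964 of Cartpt, replicate 2 had 16650 detected genes and 5.592 CPM of Adgrd1, replicate 3 held 251 of Ttc7b and replicate 5 held 0.4382 of Bdnf. At 1 month, saline replicate 2 held 238.7 CPM of Nnat, 12.45 of Cartpt and 1.973 of Bdnf, and saline replicate 5 had 20.25% of read pairs outside genes. Escalating replicate 4 at 1 month had 15600 detected genes, 10.95% of its counts on 45S ribosomal RNA, and 13.46 CPM of Fos, 50.84 of Fosb and 37.14 of Npas4. The nonescalating-minus-saline difference of Ttc7b was negative at 24 h and near 0 at 1 month, so its signed value was higher at 1 month by 1.1 on the log2 scale. Of the 30 splits of the libraries drawn for that comparison, the real one included, 5 called at least its 1 gene. The highest other called 170, so chance is not excluded. A count of 170 may come from a structure of the samples, which was not tested.

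The 6 genes lower after cocaine than after saline at 24 h rest on the saline libraries. Without saline replicate 5, Ttc7b kept its call (adjusted p = 0.016), which argues against that library as its source. The median log2 fold change of the other 5 genes went from -2.26 to -0.925 and none stayed called: Nnat, Mmp24 and Adgrd1 lost much of their fold, while Klf7 (-1.29 to -0.93) and Pde4a (-0.90 to -0.76) kept most of it. With the glial marker covariate 4 of the 6 were still called, which leaves RNA of glial cells open. Of 30 splits, 2 gave at least 6 genes and the highest other gave 19, so chance is not excluded. At 1 month saline libraries held on average 217 CPM of Ttc7b, 80.2 of Pde4a and 52.35 of Klf7. They held 16.15 of Mmp24, 5.18 of Adgrd1 and 106 of Nnat. These means lay near the nonescalating ones at 24 h (215, 76.1, 56.3, 16.4, 5.01 and 99.6). The escalating means at 24 h were 208, 77.1 and 51.2 for Ttc7b, Pde4a and Klf7, so for these genes the saline 24 h group is the one apart. For Mmp24, Adgrd1 and Nnat the escalating means at 24 h were lower, at 10.7, 2.38 and 27.7. Saline replicate 5 at 24 h lay far above the other saline libraries for these genes, so that library more than its group is apart. A response to cocaine stays open, but these levels do not tell it from a departure of the saline 24 h libraries.

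The genes that differed between saline libraries at 1 month and at 24 h were summarised by 1 score per library. The score moved between the times by 0.0105 ± 0.0699 in nonescalating libraries (unadjusted exact permutation p = 0.878). In escalating libraries it moved by 0.202 ± 0.0648 (unadjusted exact permutation p = 0.0317), in the direction of the saline move. These values argue against a difference between the sets of libraries that moved every group by the 1.38 of the saline libraries. That saline move is no test, since the genes were chosen on the same libraries and selection inflates it, so a smaller difference between the sets stays open. Without saline 24 h replicate 5 the fold changes had a median ratio of 0.85 to those with it, and 45 of the 128 genes were still called, which leaves that library open as a part of the difference. Of 30 splits only the real 1 gave as many as 128 genes, and the highest other gave 37. That is the lowest share that 30 splits can give, and it was not corrected for the other comparisons split in this way. Moreover, 2 of the 30, the real 1 included, gave at least its 2486 genes at an unadjusted p under 0.05. The SD of the score was 0.724 in saline libraries at 24 h, against 0.106 at 1 month and 0.0797 to 0.168 in the cocaine groups. A fit with 1 spread per gene for all groups may therefore understate the error of this comparison. A fit of the saline groups alone called 0, so chance is not firmly excluded.

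Ribosomal protein and oxidative phosphorylation genes were higher as groups in escalating than in nonescalating libraries at 24 h by camera, with adjusted p = 0.975 for both with an estimated correlation. Exact permutation tests of the mean level of each list gave p = 0.0944 and 0.0974, so variation between libraries that the genes share cannot be told apart from a group difference with 5 and 9 libraries. The difference leaned on the second nonescalating run: it was 0.272 for the ribosomal and 0.255 for the oxidative phosphorylation score, 0.175 and 0.133 against the first run (exact permutation p = 0.268 and 0.294) and 0.465 and 0.50 against the second (0.0714 and 0.0536 by the same exact test). The glial score carried 0.00443 ± 0.0199 of the 0.272, which argues against RNA of glial cells as the source of the ribosomal difference. A difference between the runs and a change with escalation of intake both stay open.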

How the results depend on the processing

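The tests with a robust estimate of the spread and without the 45S ribosomal RNA were chosen only after the results were seen; they gave 5 and 6 genes for all cocaine at 24 h, 129 and 143 between saline times and 730 and 713 for purified RNA. No result reversed, which for genes and library values means a change of sign with at least 1 of the 2 fits or tests passing. Signs of values that passed in neither could change. For example, Fos in all cocaine at 1 month went from -0.11 to 0.66 without saline replicate 1. For named genes 4415 values kept their side of the threshold, 191 lost and 54 gained a call. For list calls 710 kept and 256 lost it, and 96 of 96 library values kept theirs. The 1 month comparisons gave 0 genes under every alternative run. DESeq2 called 47 genes for escalating against saline at 24 h, 117 for nonescalating, 171 for all cocaine, 2 and 73 for the escalating and nonescalating differences between the times and 628 between saline times. For purified against input RNA it called 938, 45.8% of them lower against 60.4% of 712, while size factors gave 67.6% lower, a filter at mean CPM of 5 gave 457 (53.6%) and saline 1 month alone 2951 (44.3%). Saline 24 h alone gave 12, all lower. With all 39 immunopurified libraries in 1 fit the 24 h counts were 43, 276 and 508 for escalating, nonescalating and all cocaine against saline and 2 for escalating against nonescalating. Size factors gave 26 for all cocaine at 24 h, 2 for the nonescalating difference and 222 between saline times. No filter gave 71 and 55 for all cocaine and saline times, and the CPM filter 30, 4 and 215 for all cocaine, the nonescalating difference and saline times. The glial covariate gave 2 for nonescalating against saline at 24 h. The first numbering run alone gave 0 for all cocaine at 24 h and 0 for the nonescalating difference, and the second run alone 0 and 2, and 1 for escalating against nonescalating at 24 h. Saline times gave 0 with only the 2 saline groups in the fit. Replicate numbers do not pair the libraries (mean correlation of deviations from the group mean 0.0186 at 24 h and -0.0289 at 1 month for the same number, 0.00562 and 0.00566 for different ones). With a replicate block the counts were 0 for all cocaine at 24 h, 0 for the nonescalating difference, 53 between saline times and 1935 for purified RNA. Except where fewer libraries were used, the cause was not tested. Camera with an estimated correlation and fry each called 0 lists in every cocaine and time comparison that had list calls, and 6 and 12 against 19 for purified RNA. The correlation of the cocaine groups' fold changes was 0.0437 and 0.0345 with divided saline libraries, and that of nonescalating fold changes between the times -0.192 with the CPM filter. Leaving out 1 library gave 0 to 2 genes for nonescalating against saline at 24 h, 0 to 89 for all cocaine at 24 h, 0 to 1 and 0 to 19 for the escalating and nonescalating differences, 7 to 379 between saline times and 43 to 2302 for purified RNA, and 0 to 0 in the other comparisons. Single libraries were left out only from compared groups of at most 5, so no nonescalating library was left out. A sex term was not run, since all libraries held 549 to 2558 Y-linked counts and at most 33 of Xist. With 5394332 counts in the smallest library, genes with few counts are imprecise.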

Other observations

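The test of nuclear RNAs, and the choice of the ion channel and vesicle genes named here, came only after the results were seen.

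Potassium channel genes were not called as a group after cocaine at 24 h (camera 0.17, and 0.922 with an estimated correlation), with negative fold changes in 42 of 63 members. Kcna2 (log2 fold change -0.45 ± 0.11), Kcng3 (-1.62 ± 0.42), Kcnc1 (-0.57 ± 0.15), Kcna6 (-0.98 ± 0.29), Kcng2 (-3.77 ± 1.13) and Kcnk2 (-1.004 ± 0.304) were lower when adjusted over the list alone. None passed over all genes (Kcna2 adjusted p = 0.107). In saline libraries, Syn1 (-0.81 ± 0.20), Syn3 (-0.80 ± 0.21) and Kcng3 (-1.88 ± 0.43) were lower at 1 month than at 24 h.

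RNAs known to stay in the nucleus were examined because noncoding RNAs were among the genes lower in purified RNA. The other nuclear RNAs had a median log2 fold change of -1.71, with 13 of 16 negative and 5 called lower: Malat1 (-2.16), Snhg14 (-1.46), Sox2ot (-3.66), Firre (-3.01) and Ftx (-3.94). Loss of nuclear RNA in the purification may explain this. RNA of other cell types was also lower in purified RNA, and the contribution of each cannot be told apart here.

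The nonescalating libraries of the first and the second run were compared at each time. At 24 h edgeR called 0 genes (986 of 13347 at an unadjusted p under 0.05, 7.39%), which leaves a difference between the runs open with 6 and 3 libraries. The glial score there was 0.403 ± 0.373 in the first and 1.29 ± 0.741 in the second run, and the share of read pairs outside genes 15.8% ± 1.39 and 22.7% ± 5.07 (SD), a difference that was not tested. At 1 month it called 0 (399 of 13293, 3%), which argues against a difference that moves many genes. A difference in fewer genes is not excluded, since the recovery of true changes was not simulated for these 6 and 5 libraries. DESeq2 was not run here. Every split gives at least a real count of 0, so the 30 of 30 splits at each time say nothing about chance; the highest other was 15 and 1. The 15 against 0 may come from a structure of the samples at 24 h, which was not tested.

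With the times averaged, edgeR called 1 gene between cocaine and saline, Nnat (-2.19 ± 0.39, adjusted p = 0.0194), and Ttc7b was at -0.47 ± 0.10 (0.137). Nnat rests largely on saline 24 h replicate 5, which held 3079 CPM against at most 244 in the other saline libraries of that time, and without it the fold change at 24 h went from -3.78 to -0.94. Of 15190 genes 1520 had an unadjusted p under 0.05. Of 30 splits 6 gave at least 1 gene and the highest other gave 25, so chance is not excluded. The 25 may come from a structure of the samples, which was not tested.

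In the other comparisons the real count was 0, which 30 of 30 splits reach by construction, so these splits say nothing about chance. The highest other was 0, 1 and 0 at 24 h for escalating against saline, nonescalating against saline and escalating against nonescalating. At 1 month it was 0, 80, 31 and 0 for escalating against saline, nonescalating against saline, escalating against nonescalating and all cocaine. The counts of 80 and 31 against 0 may come from a structure of the samples, which was not tested. For the escalating difference between the times and that between the cocaine groups the highest other was 0. Only 30 splits were drawn per comparison because of the limit on repeated fits.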
